A study of Mus musculus with 7 samples.

How the data were processed

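Brain cells of mice that had undergone sham surgery (Sham) or surgery for myocardial infarction (MI) were profiled by droplet single-cell RNA sequencing. Per the labels, cell suspensions were stained for CD45, a surface protein of leukocytes, and viable CD45-positive cells were sorted by flow cytometry before 10x Genomics libraries were made. The extraction text also names an RNA extraction kit and standard Illumina libraries; the deposited files are droplet single-cell matrices. There were 7 samples, 3 Sham (Sham2, Sham4 and Sham5) and 4 MI (MI1, MI2, MI3 and MI4), grouped by the treatment label and named by their titles. The deposited files number the samples titled Sham4 and Sham5 as 3 and 4. The genotype label gives an APOE4 knock-in in every sample, whereas the design text names C57BL/6 mice, so genotype was constant across the comparison as far as the labels say. The time after surgery, sex, age and sequencing batch are not given in the sources used here. The labels do not say that the samples came from separate animals, so p-values measure the spread between these samples, which may be partly technical.

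The deposited files hold unnormalised unique molecular identifier (UMI) counts per gene and barcode, per the file headers (integer matrices), for 32285 genes. Per the submitters' processing notes, Partek 10.0.22.1204 and the genome build mm10 were used, with no role stated for the tool. The aligner, the annotation, the cell calling and the handling of reads shared between genes are not given in the sources used here. Counts of near-identical genes (H2-Q4, H2-Q6 and H2-Q7, Hspa1a and Hspa1b, ribosomal proteins and their pseudogenes) and of overlapping genes are therefore uncertain. The deposited matrices contained 53126 barcodes, none with fewer than 500 UMIs. Total UMI counts per sample ranged from 39052990 (MI3) to 82563642 (MI4). Gene positions are from the GENCODE annotation of the mouse genome GRCm38 (the assembly behind mm10), matched on the Ensembl gene identifiers in the files; all 228 genes looked up were matched.

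Cells with at least 200 genes, at least 500 UMIs and at most 10% mitochondrial UMIs were kept. The mitochondrial limit removed 19.3% of barcodes in Sham2, 8.04% in Sham4, 9.73% in Sham5, 16.9% in MI1, 7.65% in MI2, 25.1% in MI3 and 12.0% in MI4. Scrublet, as run in scanpy 1.11.5, called only 27 of 46182 cells as doublets (0.0585%), so doublet calling did not work on these data. Removing the 2961 cells with the highest scores, at an assumed rate of 0.8% per 1000 barcodes, was added as an alternative. After filtering, 46155 cells remained, with a median of 5554 (Sham4) to 8356 (MI3) UMIs per cell.

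Cells of all samples were clustered together without integration, using 2000 highly variable genes, 30 principal components, 15 neighbours and Leiden clustering at resolution 1 (Python 3.11.15, scanpy 1.11.5, anndata 0.12.19, leidenalg 0.10.2, igraph 0.11.9, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3). The 27 clusters were named from marker lists of 21 cell classes. The marker lists were fixed before the data were examined, as were the samples' groups, the main tests, the gene lists, the rule for named genes and the alternatives not described below as added later. The naming thresholds were set after the clusters had been seen. A class other than microglia needed at least 3 of its markers detected (50 CPM, UMI counts scaled to 1e6 per sample) at 10-fold or more over the other clusters and a marker among the 10 leading genes. A cluster was called microglia-like when its median share of UMIs in the microglia markers was at least 50% of that of the median cell and markers of other classes did not lead it. In clusters of other classes, cells at or above the same 50% limit were set aside as mixed. Of 1099 cells in the border-associated macrophage-like clusters, 633 were set aside and 128 lay near the limit. The cells set aside had a median of 19930 UMIs and those kept 3315, so mostly shallow cells remained in this class. Of 1068 cells in the T cell-like cluster, 97 were set aside and 21 lay near the limit. The limit is a point on a continuous score. Microglia-like cluster 3 (4546 cells) lay close to it, with a median marker share of 0.590 of that of the median cell. Of its cells, 62.6% lay at or above the limit. A further rule left unnamed clusters with very low UMI counts and no leading microglia marker. Cluster 3 stayed just above that rule, at 0.352 of the sample median (2237.5 UMIs).

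Clusters 6, 8 and 10 remained unnamed. Cluster 6 (3368 cells) had a median of 1451 UMIs and matched no class. Cluster 8 (2864 cells) carried microglia markers but was led by the neural genes Slc1a2, Cpe and Aldoc. Cluster 10 (1080 cells) had a median of 1758 UMIs and was led by hemoglobin genes. Together they held 9.69% ± 3.32 of Sham cells (SD, n = 3) and 22.3% ± 5.40 of MI cells (SD, n = 4). The cluster called plasma cell-like was also led by B-cell genes (Cd79a, Ebf1), and oligodendrocyte lineage-like cells numbered only 37. The 12 other named classes entered the comparison of shares. Classes with at least 20 cells in every sample were tested for expression, which left microglia-like, border-associated macrophage-like and T cell-like cells.

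UMI counts were summed per sample and class, and over all kept cells. Differences between MI and Sham were tested with edgeR 4.0.16 (R 4.3.3), using TMM normalisation, filterByExpr and the quasi-likelihood test with Benjamini-Hochberg adjustment and a threshold of 0.05. Log2 fold changes are MI minus Sham and SE is their standard error. A test of the interaction of class and surgery, with the sample as a block, asked whether effects differed between classes. There were 19 gene lists. Those with at least 5 tested members were tested with camera in limma 3.58.1 on log2 CPM (prior count 2), with a preset inter-gene correlation of 0.01, and adjusted over the lists of a class. Camera with an estimated correlation, fry and an exact permutation test of each list's mean were run beside it. Fry tests whether a list's genes move, on balance, in one direction and does not compare them with other genes. Members of a list are named only where the list passed the main camera test, except where a gene is said to have been chosen after its values were seen. Shares of cells were compared with two-sided exact permutation tests over all 35 splits of the samples (smallest possible p = 0.0286), adjusted over the 12 classes. Intervals for the share in a single sample are exact (Clopper-Pearson, 95%) and cover counting error only.

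Where fewer than 10 genes passed, the rule named all that passed and the 5 genes of smallest unadjusted p in each direction, described as not passing. Where more passed, it named up to 12 in each direction (5 in each direction for the smaller classes). From each list the rule took up to 4 members of smallest p. Gene models without a proper name were counted but not named. Some list members that the rule would name are not reported here.

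The labels give no batch. The first principal component of the summed microglia-like counts separated 3 samples (Sham2, MI1 and MI2) from 4 (Sham4, Sham5, MI3 and MI4). These are called library set 1 and library set 2. The sets cross the surgery groups, and set 1 holds a single Sham sample. A fit with the library set as a term, and its repeats under other tools and choices of cells, were added after the data had been seen. The sets were derived from the same counts, so adjusted p-values from that fit are optimistic. Exact permutation tests within the sets have only 18 splits of the samples (smallest possible p = 0.0556).

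Alternatives were DESeq2 1.42.0, limma-voom, DESeq2 size factors or total counts in edgeR, no low-count filter, a stricter cell filter (500 genes, 1000 UMIs, 5% mitochondrial UMIs), doublets kept, Leiden resolution 2, classes by marker UMIs, the replicate number as a block, each sample left out in turn and shares among non-microglia cells. Added later were the library set term, a block by the numbers of the deposited files, mixed cells kept, all 3 unnamed clusters (cluster 6, which matched no class, included) joined to microglia-like cells, clusters 8 and 10 joined without cluster 6, and the removal of doublets at an assumed rate. A sex covariate was not run, since all samples carried the same pattern of sex-linked genes.

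The edgeR and camera steps were tested on simulated counts with the real means and library sizes, in which 100 genes were changed 2-fold and 100 genes 4-fold. With surgery alone, 55% of 2-fold and 84% of 4-fold changes were recovered among 15563 microglia-like genes, 29% and 92% among 4734 border-associated macrophage-like genes, 54% and 88% among 8049 T cell-like genes, and 54% and 64% among 17157 genes in all cells together. With the library set as a term the corresponding values were 80% and 99%, 47% and 97%, 63% and 94%, and 60% and 85%. False calls numbered between 1 of 122 calls (border-associated macrophage-like, surgery alone) and 15 of 172 (T cell-like, library set as a term). Each gene was simulated independently and the library sets were taken as known. The simulation therefore lacks variation shared between genes, and its values need not hold for camera or the fit with the library set. In it camera called 0 of 18 unaltered microglia-like lists. Other splits of the real samples gave a median of 6.5 called lists. Figures were drawn with matplotlib 3.10.9.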

Results

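The effect of myocardial infarction on leukocytes of the mouse brain was examined in sorted CD45-positive cells from 3 Sham samples and 4 MI samples. Sham surgery repeats the operation without infarction and gives the background against which MI is read. The UMI counts summed to 41496388 in Sham2, 70784205 in Sham4, 70619092 in Sham5, 57319054 in MI1, 52811873 in MI2, 39052990 in MI3 and 82563642 in MI4. After filtering, 4837, 7593 and 8068 cells remained in the Sham samples and 7271, 7038, 3222 and 8126 in the MI samples. Apoe, the mouse gene at the locus named in the genotype label, was counted at 37.9 (Sham5) to 136 (MI2) CPM in microglia-like cells and at 4081 to 9373 CPM in border-associated macrophage-like cells. These counts are assigned to the mouse gene and do not distinguish the human allele. Xist, the transcript of the inactive X chromosome, was counted at 0.260 CPM or less in microglia-like cells of every sample, and the Y-linked gene Ddx3y at 90.0 to 110 CPM. Replicates of a group differed by more than sampling noise in every pair compared (chi-square over degrees of freedom of at least 2.19), so no pair looked like copies of 1 library. This does not show that they came from separate animals.

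Microglia-like cells, the resident macrophages of the brain parenchyma, were the most abundant class in every sample. They made up 81.6% ± 3.42 of Sham cells (SD, n = 3) and 69.5% ± 5.51 of MI cells (SD, n = 4), and every MI sample lay below every Sham sample. The difference of 12.1 percentage points did not pass the exact permutation test (p = 0.0571, adjusted p = 0.514 over 12 classes). Within the library sets the difference was −6.89 percentage points in set 1 and −15.4 in set 2, and the exact test within sets gave p = 0.111. The edgeR test on cell counts placed the share past the threshold (log2 fold change −0.23, adjusted p = 0.0463). The unnamed clusters moved the other way, from 9.69% ± 3.32 in Sham to 22.3% ± 5.40 in MI (exact p = 0.0286, the smallest possible, not part of the 12 classes). They differed by 7.18 percentage points in set 1 and 16.8 in set 2, but largely through different clusters. In set 1 cluster 8 held 5.75% of Sham2, 11.4% of MI1 and 13.1% of MI2. Cluster 6 held 3.18%, 4.03% and 2.37% of these samples. In set 2 cluster 6 held 3.89% of Sham4, 5.84% of Sham5, 24.6% of MI3 and 14.7% of MI4. Cluster 8 held 1.78%, 4.73%, 2.33% and 3.03% of these. Unnamed clusters 6, 8 and 10 had median mitochondrial shares of 4.65%, 3.26% and 5.23%, against 0.903% to 3.50% in the microglia-like clusters. When all 3 unnamed clusters were counted as microglia-like, the share was 91.3% ± 1.76 in Sham and 91.8% ± 3.60 in MI, which follows from the higher unnamed share. With clusters 8 and 10 alone, which carried microglia markers, it was 87.0% ± 0.417 and 80.4% ± 8.88, a difference of −6.61 percentage points that became −2.905 without MI3. With cells assigned by marker UMIs it was 93.6% ± 1.77 and 93.8% ± 2.98.

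T cell-like cells made up 2.63% ± 0.508 of Sham cells and 1.63% ± 0.452 of MI cells (exact p = 0.0857, adjusted p = 0.514), with differences of −0.84 percentage points in library set 1 and −1.15 in set 2. Among cells other than microglia-like ones their share was 14.8% ± 4.93 in Sham and 5.45% ± 1.48 in MI (exact p = 0.0286, adjusted p = 0.314). That denominator contains the unnamed clusters. Border-associated macrophage-like cells, the macrophages of the meninges and perivascular spaces, made up 1.25% ± 1.04 and 0.986% ± 0.260 (exact p = 0.771), with differences of −1.45 percentage points in set 1 and 0.344 in set 2. Without Sham2 their difference of −0.267 percentage points became 0.306. Monocyte-like cells (0.221% ± 0.103 and 0.547% ± 0.463), neutrophil-like cells (0.105% ± 0.0186 and 0.271% ± 0.248) and astrocyte-like cells (0.0787% ± 0.0578 and 0.239% ± 0.212) had higher means in MI, each with an adjusted p of 0.823 by the exact test. Of the differences, 0.326, 0.166 and 0.161 percentage points, the first became 0.132 without MI1, the second 0.0478 without MI2 and the third 0.0646 without MI3. Within sets 1 and 2 these differences were 0.788 and −0.0881, 0.264 and 0.0580, and 0.0712 and 0.279 percentage points. The NK cell and ILC1-like, innate lymphoid cell type 2-like, plasma cell-like, conventional dendritic cell-like, neuron-like and choroid plexus and ependymal cell-like classes had an adjusted p of 1.00. Shares are those of a CD45 sort, which sets how many non-leukocytes enter.

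**Figure D1:**
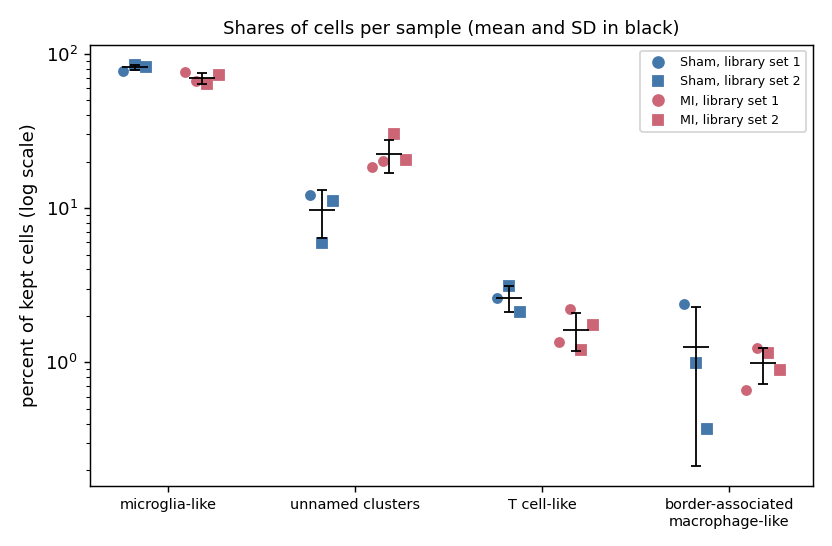
Shares of kept cells per sample on a log scale for 4 groups of cells, with each point a sample coloured by surgery and shaped by library set, and the mean and SD in black. The 4 MI samples lie below the 3 Sham samples for microglia-like cells (means 69.5% and 81.6%) and above them for the unnamed clusters (22.3% and 9.69%).

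The largest axis of variation among microglia-like cells did not follow surgery. The first principal component of the summed counts held 56.2% of the variance and separated Sham2, MI1 and MI2 (library set 1) from Sham4, Sham5, MI3 and MI4 (library set 2). The second held 15.5% and placed all 3 Sham samples on one side and all 4 MI samples on the other, with Sham4 (0.77) and MI3 (−0.53) at its ends. By chance 1 given component separates the groups in 5.71% of cases. Between the sets 4369 of 15563 genes differed in microglia-like cells (edgeR, adjusted p under 0.05), with 73 in border-associated macrophage-like cells, 121 in T cell-like cells and 5558 in all cells together. The labels name no batch, and the sets were found in these counts.

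**Figure D2:**
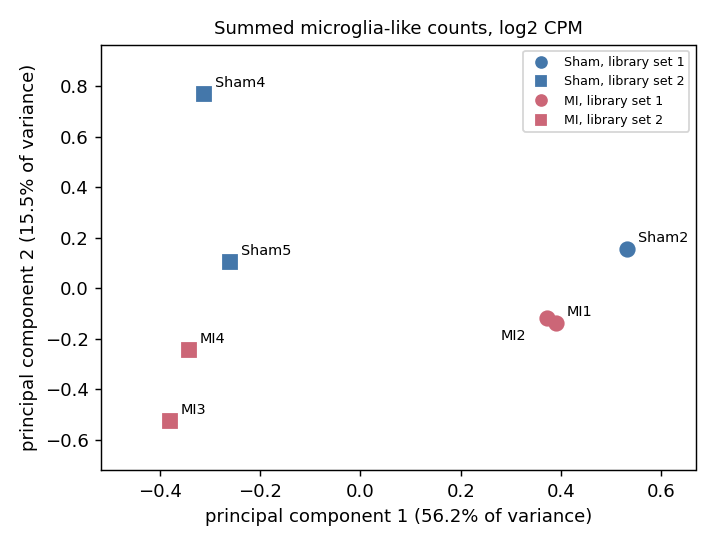
First (56.2% of variance) and second (15.5%) principal components of the summed microglia-like log2 CPM, with 1 point per sample, coloured by surgery and shaped by library set. Sham2, MI1 and MI2 lie on one side of the first component and Sham4, Sham5, MI3 and MI4 on the other. The second component has the Sham samples above and the MI samples below 0.

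Whether MI alters the transcriptome of microglia was the main comparison. With surgery as the only term no gene in microglia-like cells passed the threshold. Genes of smallest p that were higher in MI were Prune2 (log2 fold change 0.38, SE 0.08), Cd46 (0.40, SE 0.08), which encodes a complement regulator, E2f7 (1.26, SE 0.29), a cell-cycle repressor, Psma8 (0.51, SE 0.12) and Rxfp1 (0.55, SE 0.13), the relaxin receptor. Those lower in MI were Fkbp6 (−2.97, SE 0.46), Rabgef1 (−0.41, SE 0.06), Siah2 (−0.64, SE 0.12), Chka (−0.52, SE 0.10), a choline kinase, and Bcl6 (−0.56, SE 0.11), a transcriptional repressor. Adjusted p-values of these 10 genes were 0.878 to 1.00 (edgeR), so none was called. Fkbp6 was near the floor, at 1.05 ± 0.386 CPM in Sham and 0.133 ± 0.0739 in MI. Chka had a mean of 204 CPM in Sham and 142 in MI. Of 15563 genes tested with edgeR 0 passed and 500 had an unadjusted p under 0.05, 208 higher and 292 lower. DESeq2 called 27 genes (5 higher, 22 lower) and limma-voom 0. A block by sample number, for which pairing was not established, gave 96 genes with the numbers of the titles and 57 with those of the deposited files (1 and 2 residual degrees of freedom). In 338 genes every MI sample lay above every Sham sample and in 310 below, 4.16% of genes, against 5.71% by chance.

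Microglia-like cells had 114 genes past the threshold, 12 higher and 102 lower in MI, in the fit with the library set as a term. That fit was chosen after the data were seen, and the sets were derived from the same counts. Among the genes that fell were Atf3 (log2 fold change −1.37, SE 0.11, adjusted p = 0.000652), a stress-induced transcription factor on chromosome 1 (191170296 to 191218039), Creb5 (−1.07, SE 0.09), Adgre5 (−1.55, SE 0.14), which encodes CD97, and Rnf19b (−1.08, SE 0.10). Btg2, an antiproliferative early-response gene, fell by 0.93 on the log2 scale (SE 0.11), Tnfaip3, an inhibitor of NF-kB signalling, fell by 1.04 (SE 0.11), and Lmna, which encodes lamin A, fell by 0.94 (SE 0.11). Fkbp6 (−3.18), Iqcn (−1.23), Etf1 (−0.58), Srsf5 (−0.58) and Ifrd1 (−0.68) also fell. Among the genes that rose were Prune2 (0.35, SE 0.06, adjusted p = 0.0158), Arhgap15 (0.45), Zfyve28 (0.46), Cd46 (0.40) and Trim5 (0.38). The groups overlapped for Atf3 before adjustment (429 ± 250 CPM in Sham and 198 ± 106 in MI), while its differences within library sets 1 and 2 were −1.30 and −1.40. All 114 genes kept their sign in every refit with the library set. The refits shared the sets and most samples with the fit that chose these genes, so that outcome was largely fixed in advance. The count of called genes ranged from 33 without MI4 and 34 without MI3 to 276 without Sham5. It was 60 without MI2 and 389 with DESeq2. Of the 114 only 44 were called again without Sham2 (106 calls, 40 higher and 66 lower), 29 without MI4 and 30 without MI3. Surgery had a different effect in the 2 sets in 6 genes.

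The gene lists showed the clearest pattern in the immediate early and dissociation response genes, which cells induce within minutes of stimulation or tissue handling. All 26 tested members had a negative log2 fold change in MI microglia-like cells (median −0.80), and camera called the list lower (adjusted p = 2.4e-15). With an estimated correlation the call was lost (adjusted p = 0.41 with an estimated correlation; 0.51 with fry). The median was −0.84 in library set 1 and −1.12 in set 2. No member passed over all genes and 3 were lower when adjusted over the list alone. In the fit with the library set 9 members fell, and 21 were lower when adjusted over the list alone. Members of smallest p were Nr4a1 (−1.13, SE 0.22), a nuclear receptor, Egr3 (−1.18, SE 0.28), and the heat-shock genes Dnajb1 (−0.81, SE 0.20) and Hspa1a (−2.02, SE 0.62), none past the threshold over all genes. Mean log2 CPM over the list was 8.02 ± 0.459 in Sham (SD, n = 3) and 7.18 ± 0.498 in MI (SD, n = 4), a difference of −0.84. The exact permutation test gave p = 0.171 (adjusted p = 0.839), and within the library sets p = 0.0556, the smallest possible. Microglia clusters led by such genes differed between samples of the same group. Cluster 4 (led by Klf4, Fosb and Dusp1) held 51.1% of the microglia-like cells of Sham2 but 2.18% in Sham4 and 1.75% in Sham5, against 20.7%, 9.72%, 0.439% and 0.289% in MI1 to MI4. Its Sham mean of 18.3%, above the MI mean of 7.80%, became 1.96% without Sham2, below it. Cluster 1 (led by Hspa1a, Ier2 and Ccl3) held 34.9% in Sham4, 5.25% in Sham2 and 19.3% in Sham5, a mean of 19.8% that became 12.3% without Sham4, against 6.80% to 9.74% in MI.

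**Figure D3:**
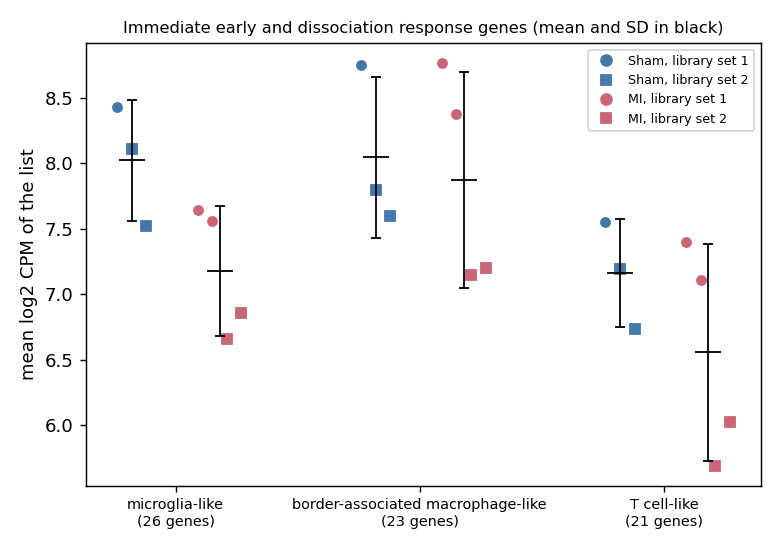
Mean log2 CPM of the immediate early and dissociation response genes per sample in 3 cell classes, with each point a sample coloured by surgery and shaped by library set, and the mean and SD in black. In microglia-like cells the MI samples lie below the Sham samples of the same library set (group means 7.18 and 8.02).

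Inflammatory cytokine and NF-kB target genes were also lower as a list in MI microglia-like cells, with 24 of 26 members negative and a median of −0.46 (adjusted p = 1.4e-11; adjusted p = 0.47 with an estimated correlation). The list's median was −0.18 in library set 1 and −0.81 in set 2. Nfkbia, the inhibitor of NF-kB (−0.77, SE 0.15), the chemokine gene Ccl7 (−1.16, SE 0.33), Nfkb2 (−0.50, SE 0.15) and Birc3 (−0.20, SE 0.07) had the smallest p. No member passed over all genes and 1 was lower when adjusted over the list alone (with the library set as a term, 1 and 12). Glucocorticoid response genes were called lower (adjusted p = 0.012; adjusted p = 0.41 with an estimated correlation) with 10 of 16 members negative and a median of −0.08, which was −0.35 in set 1 and 0.11 in set 2. Nfkbia, Per1 (−0.37), Errfi1 (−0.42) and Sgk1 (−0.43) led it, and 2 members were lower when adjusted over the list alone (with the library set as a term 2 fell; 6 were lower and 1 higher over the list alone). This list shares Nfkbia and Dusp1 with the lists above. Its members Ddit4 and Fkbp5 were among the leading genes of cluster 0. On average that cluster held 9.86% of Sham and 23.4% of MI microglia-like cells, and it was larger in library set 2. MHC class I antigen presentation was called lower (13 of 14 members negative, median −0.06, adjusted p = 0.0092; adjusted p = 0.95 with an estimated correlation), with medians of −0.17 and −0.07 in sets 1 and 2, led by H2-Q7 (−0.77, SE 0.23), H2-K1 (−0.27), H2-Q4 (−0.52) and H2-Q6 (−0.52). None of its members passed over all genes or adjusted over the list alone (with the library set as a term, 1 and 1). The exact permutation test of list means gave p = 0.171 (NF-kB targets), 0.114 (glucocorticoid response) and 0.314 (MHC class I). Each had an adjusted p of 0.839. Within the library sets the exact test gave p = 0.0556, the smallest possible, for NF-kB targets and for glucocorticoid response, and 0.222 for MHC class I.

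The other 15 lists were not called in microglia-like cells, and none of their members passed adjusted over the list alone. Homeostatic microglia genes had a median of 0.033 (camera adjusted p = 0.376) and disease-associated microglia genes −0.033 (0.376). The homeostatic list contains the microglia markers by which clusters were named microglia-like. Clusters low in these markers were left out beforehand, so the small median of that list may partly follow from the choice of cells. MHC class II antigen presentation had a median of −0.16 (0.442), complement −0.030 (0.472), and lysosome and phagocytosis −0.024 (0.467). Cell cycle genes had a median of 0.24 (0.354), nuclear-encoded oxidative phosphorylation 0.039 (0.376), mitochondrial-encoded transcripts 0.080 (0.376), glycolysis and hypoxia −0.026 (0.354) and ribosomal proteins 0.019 (0.836). The remaining 5 had a median above 0 and a mean and camera direction below 0. They were type I interferon response (median 0.016, 0.823), cholesterol synthesis and efflux (0.0075, 0.868), TGF-beta and microglial transcription factors (0.0033, 0.922), adhesion and leukocyte trafficking (0.036, 0.868), and T and NK cell activation and cytotoxicity (0.0052, 0.823).

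In border-associated macrophage-like cells 1 gene changed. Ptprk, which encodes a receptor-type tyrosine phosphatase (chromosome 10, 28074820 to 28597397, GRCm38), rose from 8.60 ± 7.48 CPM in Sham (SD, n = 3) to 94.0 ± 29.8 in MI (SD, n = 4), a log2 fold change of 2.90 (SE 0.46, edgeR adjusted p = 0.0178). The call for Ptprk in border-associated macrophage-like cells was lost with limma-voom (adjusted p = 0.82), without Sham2 (0.251), without Sham4 (0.164), with mixed cells kept (log2 fold change 1.00, adjusted p = 1.00) and with classes by marker UMIs (log2 fold change 1.495, adjusted p = 0.999), where the 1 gene called was a lower one. Of 4734 genes tested 212 had an unadjusted p under 0.05. DESeq2 called 1 gene and limma-voom 0 (264 with an unadjusted p under 0.05). Genes of smallest p that did not pass were Ahnak (1.80, SE 0.41), Ctnnd2 (1.87, SE 0.44), Cd200r1 (1.20, SE 0.34), an inhibitory receptor of myeloid cells, Prkg1 (0.99, SE 0.31) and Hgsnat (1.33, SE 0.42) on the higher side. Hgsnat rested on MI1 (398 CPM against 128 to 144 in the other MI samples). On the lower side were Tnfsf13b (−1.50, SE 0.30), which encodes the B-cell survival factor BAFF, Adgre5 (−1.59, SE 0.36), Stmn1 (−1.58, SE 0.40), Prdx1 (−1.06, SE 0.27) and Anxa5 (−0.95, SE 0.24). Adding the library set, Ptprk rose (2.94) and Tnfsf13b (−1.50), Adgre5 (−1.60), Atf3 (−1.18) and Prdx1 (−1.15) fell, 5 genes in all. That count was 0 without Sham2, 9 without Sham5, 10 without MI2, 2 without MI4, 3 without Sham4 or without MI3, and 33 with mixed cells kept. Of the 5 genes, 5 were called again without Sham5, 3 without MI2 and 2 without MI3. Only 1 was called again without Sham4, without MI4 or with mixed cells kept, and 0 with classes by marker UMIs (6 calls). These sums held only 82385 (Sham5) to 679404 (Sham2) UMIs from 30 to 116 cells.

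Camera called antigen presentation genes lower as lists in MI border-associated macrophage-like cells. All 8 tested MHC class II genes were negative (median −0.31; −0.23 in library set 1 and −0.43 in set 2), led by Cd74 (−0.64, SE 0.24), H2-Eb1 (−0.59, SE 0.23), H2-Aa (−0.50) and H2-Ab1 (−0.38), with a camera adjusted p of 0.013 (adjusted p = 0.93 with an estimated correlation). MHC class I genes were negative in 12 of 13 (median −0.40; −0.44 and −0.41 in the sets; adjusted p = 0.016, and adjusted p = 0.93 with an estimated correlation), led by H2-Q4 (−1.08), H2-K1 (−0.54), Tap2 (−0.64) and H2-Q7 (−0.92). NF-kB target genes were negative in 14 of 19 (median −0.61; −0.69 and −0.29; adjusted p = 0.013, and adjusted p = 0.93 with an estimated correlation), led by Birc3 (−0.82), Nfkb1 (−0.61), Nfkbia (−0.65) and Il1b (−1.09). Cholesterol synthesis and efflux genes were higher, 9 of 12 positive (median 0.27; 0.55 and 0.17; adjusted p = 0.024, and adjusted p = 0.64 with an estimated correlation), led by Msmo1 (1.08, SE 0.36), Idi1 (1.15), Srebf2 (0.64) and Fdps (1.01). Ribosomal protein genes were positive in 48 of 49 (median 0.17; 0.35 and −0.07; adjusted p = 0.015, and adjusted p = 0.94 with an estimated correlation), led by Rpl5 (0.45), Rpl4 (0.34), Rps14 (0.28) and Rps16 (0.26). No member of these 5 lists passed over all genes or adjusted over the list alone. The exact permutation test of list means gave p = 0.114 for MHC class II, 0.371 for class I and 0.543 for NF-kB targets. It gave 0.0286, the smallest possible, for cholesterol genes and 0.429 for ribosomal protein genes (adjusted p = 0.514 to 0.971). The NF-kB call was lost without Sham2 (adjusted p = 0.969), and the ribosomal call in the fit with the library set (0.141), which kept the other 4. With classes by marker UMIs only the MHC class II and class I calls remained, and the ribosomal list changed direction (0.309). With mixed cells kept, the MHC class II, cholesterol and ribosomal lists changed direction without passing (adjusted p = 0.458, 0.809 and 0.403).

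Of the lists not called in these macrophages, the immediate early and dissociation response genes had a median of −0.10 (camera adjusted p = 0.196), against −0.80 in microglia-like cells. They were called lower in the fit with the library set (adjusted p = 2.2e-05; adjusted p = 0.45 with an estimated correlation). Homeostatic microglia genes had a median of 0.17 (0.235), disease-associated microglia genes −0.13 (0.650), type I interferon response 0.090 (0.894), oxidative phosphorylation −0.090 (0.614), mitochondrial-encoded transcripts 0.18 (0.196), glycolysis and hypoxia −0.19 (0.708), complement −0.013 (0.824), lysosome and phagocytosis 0.11 (0.769), and T and NK cell activation −0.51 (0.176). Glucocorticoid response genes had a positive median (0.14) beside a negative mean and camera direction (0.222), and 1 member was lower adjusted over the list alone. TGF-beta and microglial transcription factors (median 0.11, 0.894) had a positive mean and a negative camera direction, and adhesion and leukocyte trafficking (median 0.034, 0.894) a negative mean and a positive camera direction. The cell cycle list had only 4 tested members. Cells high in the microglia markers, which belong to the homeostatic list, had been set aside from this class, so the value of that list depends on this choice.

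Camera called microglia genes lower as lists in T cell-like cells of MI samples. All 17 tested homeostatic microglia genes were negative (median −0.49; −0.37 in library set 1 and −0.54 in set 2; camera adjusted p = 7.2e-10, and adjusted p = 0.36 with an estimated correlation), and 3 were lower when adjusted over the list alone. Cx3cr1, the fractalkine receptor, was counted at 172 ± 31.2 CPM in Sham and 105 ± 11.4 in MI (−0.71, SE 0.17), Olfml3 at 46.2 ± 7.30 and 22.9 ± 9.11 (−0.91), and Csf1r at 118 ± 18.1 and 75.2 ± 29.6 (−0.65). The 12 microglia markers held 0.105% ± 0.0188 of T cell-like UMIs in Sham and 0.0702% ± 0.0232 in MI. Lists of other macrophage genes were lower too, with 18 of 21 lysosome and phagocytosis genes negative (median −0.30; −0.04 and −0.43 in the sets; adjusted p = 1.9e-06, and adjusted p = 0.36 with an estimated correlation), among them Mertk (−1.04) and Fcgr3 (−0.83). All 5 complement genes were negative (median −0.64; −0.44 and −0.90; adjusted p = 0.00045, and adjusted p = 0.36 with an estimated correlation; Itgam −0.51, C1qb −0.79, C1qc −0.63). TGF-beta and microglial transcription factors were negative in 14 of 17 (median −0.18; −0.28 and −0.24; adjusted p = 0.0042, and adjusted p = 0.40 with an estimated correlation; Spi1 −1.09, Maf −0.51, Sall1 −0.57) and disease-associated microglia genes in 10 of 14 (median −0.25; 0.0010 and −0.44; adjusted p = 0.029, and adjusted p = 0.45 with an estimated correlation; Ctsz −0.58, Trem2 −0.57, Ctsb −0.40, Ctsd −0.30). No member of these 4 lists passed adjusted over the list alone. For them and the homeostatic list the exact permutation test of list means gave p = 0.114 to 0.229 (adjusted p = 0.514 each). With the library set the disease-associated call was lost (0.0572). With classes by marker UMIs all 5 of these calls were lost (adjusted p = 0.469 for homeostatic microglia, 0.0902 to 0.749 for the others), TGF-beta and microglial transcription factors changed direction, and so did Cx3cr1 (0.12) and Itgam (0.15).

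Immediate early and dissociation response genes were also called lower in T cell-like cells (18 of 21 negative, median −0.33; −0.27 and −0.98 in the library sets; adjusted p = 1.9e-06, and adjusted p = 0.40 with an estimated correlation), with 2 lower when adjusted over the list alone. Atf3 did not pass over all genes (−2.43, SE 0.51, edgeR adjusted p = 0.648), nor did Rhob (−0.82, SE 0.21), Ier5 (−0.52) or Ier2 (−0.65). Glucocorticoid response genes were negative in 9 of 10 (median −0.31; −0.37 and −0.42; adjusted p = 0.0042, and adjusted p = 0.36 with an estimated correlation), with Sgk1 (−0.58), Nfkbia (−0.44), Per1 (−0.49) and Tsc22d3 (−0.27). Adhesion and leukocyte trafficking genes were negative in 12 of 15 (median −0.10; −0.24 and −0.05; adjusted p = 0.049, and adjusted p = 0.36 with an estimated correlation), with 2 lower adjusted over the list alone. They were led by Cx3cr1, Cxcr4 (−0.94), Icam1 (−0.40) and S1pr1 (−0.22). Ribosomal protein genes were positive in 48 of 49 (median 0.11; 0.20 and −0.10; adjusted p = 0.029, and adjusted p = 0.85 with an estimated correlation), with Rpl10 (0.19), Rps12 (0.21), Rps2 (0.17) and Rps19 (0.16); Rps2 became −0.029 and Rps19 −0.022 without MI1. The ribosomal list was not called without Sham4 (adjusted p = 0.987) or with the library set (0.476). With classes by marker UMIs only the immediate early call remained of the 9 T cell-like lists (adjusted p = 0.00582). No member of the glucocorticoid or ribosomal list passed adjusted over the list alone. The exact permutation test of list means gave p = 0.314 for immediate early and 0.0571 for glucocorticoid response genes. It gave 0.0286 for adhesion and 0.743 for ribosomal protein genes (adjusted p = 0.514 to 0.943 for all of these).

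Lists not called in T cell-like cells were T and NK cell activation and cytotoxicity (median −0.18, camera adjusted p = 0.194), inflammatory cytokines and NF-kB targets (−0.11, 0.194), mitochondrial-encoded transcripts (0.11, 0.102), oxidative phosphorylation (0.050, 0.342), type I interferon response (0.049, 0.559) and cholesterol synthesis and efflux (−0.0091, 0.371). MHC class I (median 0.0012, 0.960) and glycolysis and hypoxia (0.019, 0.980) had a negative mean beside a positive median and camera direction, and cell cycle (0.075, 0.317) a positive median beside a negative mean and camera direction. No member of these lists passed adjusted over the list alone, and MHC class II had only 3 tested members. Over all genes, edgeR called 0 of 8049 in T cell-like cells, with 261 at an unadjusted p under 0.05, and DESeq2 and limma-voom each called 0. The genes of smallest p besides those above were Bckdk (1.56, SE 0.43), Acvr2a (1.01), Acss2 (0.93), Mthfsl (0.81) and Cfap36 (0.77), and Rapgef5 (−1.13) and Mast4 (−1.69), none of which passed. Leaving out MI4 gave 3 calls, and leaving out Sham5 or MI1 gave 1 each. With the library set as a term Junb (−1.07, SE 0.16, adjusted p = 0.0070), an AP-1 subunit, Tnfaip3 (−0.88, SE 0.14) and Trdc (−2.26, SE 0.40), the constant region of the T cell receptor delta chain, fell. That count of 3 became 0 without Sham4 or MI3, 5 without Sham5 and 10 without MI2. Of the 3 genes, 3 were called again without Sham5, 2 without MI1 or MI2 and 1 without Sham2 (4 calls). Without MI4 (3 calls) or with mixed cells kept (1 call), 0 were called again.

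Summed over all kept cells, which mixes composition and expression, edgeR called 0 of 17157 genes, with 439 at an unadjusted p under 0.05; DESeq2 called 27 and limma-voom 0. The genes of smallest p were largely those of microglia-like cells, with Prune2 (0.38), Rap1gap2 (0.43, SE 0.09), Cd46 (0.43), Sgip1 (0.47) and Psma8 (0.51) higher and Fkbp6 (−2.87), Rabgef1 (−0.37), Zbtb2 (−0.52, SE 0.08), Siah2 (−0.62) and Trp53inp2 (−0.61) lower, none past the threshold. With the library set as a term 34 genes passed, 2 higher and 32 lower. Rap1gap2 rose (0.39). Creb5 (−0.99), Atf3 (−1.36), Rnf19b (−1.03), Fkbp6 (−3.05), Tmem88 (−2.24), Tnfaip3 (−1.05), Iqcn (−1.18), Etf1 (−0.55), Zbtb2 (−0.53) and Kdm6b (−0.98), a histone demethylase, fell, as did the chemokine gene Ccl5 (−0.79) and the T cell receptor gene Trbc2 (−0.71), both expressed by T cells. The count was 0 without MI3 or MI4, 7 without Sham2, 10 without MI2 and 22 without MI1.

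Whether the effect of surgery differed between classes was tested directly. Between border-associated macrophage-like and microglia-like cells 20 genes differed (edgeR interaction), 9 with a higher and 11 with a lower effect in the macrophages. Ier2 (difference 1.80, SE 0.27) and Nfkbiz (1.36, SE 0.24) had a higher effect there. Tnfsf13b had a lower one (−1.86, SE 0.30), with log2 fold changes of −1.50 in macrophages and 0.37 in microglia-like cells, as did Prdx1 (−1.09, SE 0.22). Between T cell-like and microglia-like cells 14 genes differed, 9 higher and 5 lower. Id2 (0.67, SE 0.13) and Mertk (−1.04, SE 0.23) were among them, as was Cd3g (2.52, SE 0.42), a T cell receptor subunit. Cd3g had a log2 fold change of 0.0058 in T cell-like cells, so its difference came from a lower value in the microglia-like sums of MI. That difference does not show an effect of MI on T cells. Doublets or free T cell RNA in those sums were not tested for this gene. The first count was 8 without MI3, 9 without MI1 and 12 without Sham4. The second was 4 without Sham5, 5 without MI1, 6 without MI3, 7 without Sham4 and 41 without MI4. The interaction test was not repeated with mixed cells kept or with classes by marker UMIs.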

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

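The tests of splits for microglia-like, T cell-like and all-cell genes, all tests within the library sets, the tests of the immediate early list and both tests of the microglia-like share were chosen after the results had been seen. The other tests in this part were written down before. Samples far from the rest of their group were found with Dixon's test at the 95% level, which flagged 9 of 117 groups of 4 MI samples. Chance flags about 1 in 20 groups, or 5.85 here.

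MI2 lay far from the other MI samples in 4 shares of cells, each with an interval for counting error. Innate lymphoid cell type 2-like cells made up 0.398% of MI2 (95% interval 0.265 to 0.574) and 0.0413% to 0.0931% of the others. Plasma cell-like cells made up 0.7104% (0.528 to 0.936) and 0.186% to 0.275%. Conventional dendritic cell-like cells made up 0.682% (0.503 to 0.903) and 0.234% to 0.275%. Neuron-like cells made up 2.53% (2.18 to 2.92) and 0.0246% to 0.248%. In MI3 the unnamed clusters held 30.3% of cells (28.7 to 31.9), against 18.4% to 20.3% in the other MI samples. MI1 lay apart in the mean of the glycolysis and hypoxia genes in T cell-like cells (6.32 log2 CPM, others 6.17 to 6.18) and in Hgsnat in border-associated macrophage-like cells (398 CPM, others 128 to 144). Anxa5 in border-associated macrophage-like cells lay apart in MI2 (217 CPM, others 163 to 172). Rabgef1 in all cells lay apart in MI4 by a small amount (36.88 CPM, others 36.58 to 36.63).

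A test of the difference between classes flagged 20 genes between border-associated macrophage-like and microglia-like cells and 14 between T cell-like and microglia-like cells. Among the flagged genes, some immediate early genes had a higher effect of MI in the macrophages than in microglia-like cells. They were Ier2 (difference 1.80 on the log2 scale, edgeR adjusted p = 2.8e-07), Klf4 (1.17, 0.0277), Egr1 (1.08, 0.0165) and Dusp1 (1.02, 0.0483). Their list as a whole was not tested for a difference between classes. Nfkbiz also had a higher effect in the macrophages (1.36, 9.5e-05), while Stmn1 had a lower one (−1.79, 0.0277). T cell-like cells had a higher effect than microglia-like cells in Nfkbiz (0.96, 0.00890), Klf2 (0.76, 0.0426) and H2-Q7 (0.78, 0.000777), and a lower one in Mertk (−1.04, 0.0152) and Ccl12 (−3.29, 0.0392). Of 35 splits of the samples, 11 gave at least 20 genes in the first comparison (highest other 46) and 15 gave at least 14 in the second (highest other 69), so chance is not excluded for either count. Both highest splits were the library sets, which were found in the microglia-like counts used here, and with the library set as a term the counts were 20 and 14.

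With surgery alone the real count of genes was 0 in microglia-like, T cell-like and all cells, which all 35 of 35 splits reach, so the splits decide nothing there (highest other 3638, 108 and 4761). In border-associated macrophage-like cells 8 splits gave at least the real count of 1 (highest other 64), so chance is not excluded. Each of these highest splits was the library sets; for microglia-like and all cells this follows from how the sets were found and is no further support for them. Chance is also not excluded for the counts of lists. Of the splits, 32 gave at least the 4 called in microglia-like cells (highest 13), 12 at least the 5 in border-associated macrophage-like cells (highest 9) and 7 at least the 9 in T cell-like cells (highest 11). Within the library sets there are too few splits (18) for a test. The real counts and highest others were 114 and 1 in microglia-like cells (reached in 1 split, the real one), 5 and 6 in border-associated macrophage-like cells (2 splits), 3 and 3 in T cell-like cells (3 splits) and 34 and 1 in all cells (1 split).

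The lower immediate early and dissociation response genes in MI microglia-like cells have 2 technical explanations that could be tested. The list's median was below −0.2 in both library sets (the higher was −0.84, in set 1), the outcome written against unequal library sets. Set 1 holds 1 Sham sample, Sham2, whose list mean of 8.43 log2 CPM was the highest of all samples. The sets came from the same counts, and the exact test within them cannot go below p = 0.0556. Unequal library sets are therefore not excluded. Handling of the cell suspension, which induces these genes, predicts the same drop in the other classes. The higher camera adjusted p in those classes was 0.196 (border-associated macrophage-like cells). Camera called the list lower in T cell-like cells and, with the library set as a term, in the macrophages. The list's mean differences in sets 1 and 2 were −0.18 and −0.52 in the macrophages and −0.30 and −1.11 in T cell-like cells. These calls were lost with an estimated correlation, and the macrophage list changed direction with classes by marker UMIs, so the test cannot tell. A difference caused by surgery stays open, and the time from death to sorting is not given.

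The smaller microglia-like share in MI could come from clusters kept unnamed. Adding all 3, cluster 6 without a class included, gave a difference of 0.523 percentage points, but shares sum to 100, so that outcome was fixed in advance and decides nothing. With clusters 8 and 10 alone the difference was −6.61 percentage points, within the SD of the MI samples (8.88), and −2.905 without MI3; with cluster 6 alone it was −4.955 (−0.883 without MI2), so the explanation stays open. Within the library sets the difference nearest 0 was −6.89 percentage points, which met the outcome written against unequal library sets. It came from a set with 1 Sham sample (Sham2, 77.9%), against 75.7% in MI1 and 66.4% in MI2, so it rested largely on MI2. Nor did the exact test within the sets pass, so unequal library sets are not excluded. Whether more unnamed cells in MI reflect the tissue or its dissociation was not tested.

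The lower microglia genes in MI T cell-like cells could come from free RNA or fragments of microglia, which would enter other classes too. The share of UMIs in microglia markers was higher in MI in 2 of the 4 other classes tested, NK cell and ILC1-like (0.0406% ± 0.0186 and 0.0676% ± 0.0484) and conventional dendritic cell-like cells (0.146% ± 0.0587 and 0.294% ± 0.168), and lower in plasma cell-like (0.133% ± 0.0931 and 0.0755% ± 0.0374) and neutrophil-like cells (0.123% ± 0.115 and 0.0642% ± 0.0266). That met the outcome written down against this explanation, but all 4 differences lay within the larger SD, and the test was read as unable to tell. With classes by marker UMIs the log2 fold change of Cx3cr1 turned from −0.71 to 0.12. Cx3cr1 is itself a microglia marker used in that assignment, so cells rich in it leave the T cell-like class by construction. The turn therefore decides nothing here. A difference in the T cells themselves stays open.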

How the results depend on the processing

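The fit with the library set as a term, and its repeats, were chosen after the data were seen, as were the tests with mixed cells kept, with unnamed clusters added to microglia-like cells, with a block by file numbers, with doublets removed at an assumed rate and with splits within the library sets. In this part macrophage-like means border-associated macrophage-like. The cause of a change was not tested unless one is given. For the named genes, microglia-like values kept direction and side of the threshold in 524 comparisons and newly passed it in 26, T cell-like values in 875 and 12 (8 reversed), macrophage-like values in 575 and 16 (5 reversed, 5 lost the call) and values of all cells together in 164 and 16. In the fit with the library set the calls were kept in 274 and lost in 32 microglia-like comparisons, kept in 40 and lost in 38 macrophage-like ones, kept in 34 and lost in 19 T cell-like ones and kept in 121 and lost in 60 of all cells together. Called lists kept the call in 73 microglia-like comparisons and lost it in 15, against 63 and 32 in macrophage-like cells (5 reversed) and 135 and 58 in T cell-like cells (5 reversed). A sex covariate was not run because the samples did not differ in sex-linked genes. For macrophage-like expression the stricter cell filter and Leiden resolution 2 were not run because a sample had fewer than 20 cells. Macrophage-like sums were shallow (82385 UMIs in Sham5), and only 4734 genes could be tested.

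The number of genes called by DESeq2 was 27 in microglia-like cells and 27 in all cells, and with the library set 389 in microglia-like cells, 2 in macrophage-like cells and 364 in all cells. With limma-voom the counts were 0 in macrophage-like cells and, with the library set, 0 in macrophage-like cells and 8 in all cells. Surgery alone gave 0, 1, 0 and 0 genes in microglia-like, macrophage-like, T cell-like and all cells, and the library set as a term gave 114 in microglia-like cells, 5 in macrophage-like cells, 3 in T cell-like cells and 34 in all cells. Without a low-count filter the counts were 30 in macrophage-like cells and 15 in T cell-like cells, and 13 genes differed in effect between macrophage-like and microglia-like cells. Total counts alone left 1 in macrophage-like cells with the library set. Keeping mixed cells gave 0 in macrophage-like cells and, with the library set, 33 in macrophage-like cells and 1 in T cell-like cells; the mixed cells carry microglia transcripts by construction. The stricter cell filter gave 62 in all cells with the library set.

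The difference in the microglia-like share (−12.1 percentage points) was 0.184 with classes by marker UMIs and 0.523 with all 3 unnamed clusters added, cluster 6 included, which by construction moves the unnamed cells into the class; edgeR on cell counts called it (log2 fold change −0.231). The difference in unnamed cells (12.6) lost its call at 11.5 with doublets kept, 8.69 at Leiden resolution 2, 0.0575 with marker UMI classes, 21.3 among cells other than microglia-like ones and 12.01 with splits within the library sets, where 18 splits cannot pass. Plasma cell-like shares turned to −0.00454 with the stricter filter, −0.00439 with marker UMI classes, −0.0144 with mixed cells kept and −0.703 among non-microglia cells, where innate lymphoid cell type 2-like cells turned to −0.111. NK cell and ILC1-like shares turned from near 0 to 0.0131 at Leiden resolution 2, 0.000628 with mixed cells kept and a log2 value of 0.000753 with edgeR on cell counts.

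With surgery alone no list was called with an estimated correlation or with fry (0, 0 and 0 lists against 4, 5 and 9 in microglia-like, macrophage-like and T cell-like cells). With the library set fry called 1 list, inflammatory cytokines and NF-kB targets, lower in T cell-like cells (adjusted p = 0.0185), and an estimated correlation 0. Marker UMI classes gave 2 in macrophage-like cells and 1 in T cell-like cells, and doublets removed at an assumed rate 5 in T cell-like cells. Lists that changed direction are given with their adjusted p. With the library set these were in microglia-like cells nuclear-encoded oxidative phosphorylation (0.959) and ribosomal proteins (0.529), then in macrophage-like cells lysosome and phagocytosis (0.932) and adhesion and leukocyte trafficking (0.917), then in T cell-like cells MHC class I antigen presentation (0.883) and nuclear-encoded oxidative phosphorylation (0.839). Marker UMI classes turned in microglia-like cells type I interferon response (0.938), MHC class II antigen presentation (0.316) and adhesion and leukocyte trafficking (0.938), then in macrophage-like cells immediate early and dissociation response (0.977), ribosomal proteins (0.309) and adhesion and leukocyte trafficking (0.607), then in T cell-like cells type I interferon response (0.749), MHC class I antigen presentation (0.390), nuclear-encoded oxidative phosphorylation (0.749), glycolysis and hypoxia (0.749) and TGF-beta and microglial transcription factors (0.749), and the log2 fold changes of Rps16 (macrophage-like cells, −0.013), Cx3cr1 (T cell-like cells, 0.12) and Itgam (T cell-like cells, 0.15). Keeping mixed cells turned in macrophage-like cells MHC class II antigen presentation (0.458), cholesterol synthesis and efflux (0.809), lysosome and phagocytosis (0.714), ribosomal proteins (0.403), TGF-beta and microglial transcription factors (0.442) and adhesion and leukocyte trafficking (0.933), then in T cell-like cells T and NK cell activation and cytotoxicity (0.888), and the log2 fold changes of H2-Ab1 (macrophage-like cells, 0.049), Idi1 (macrophage-like cells, −0.066), Fdps (macrophage-like cells, −0.16) and Rpl4 in border-associated macrophage-like cells (−0.015). Without a low-count filter, with border-associated macrophage genes of low counts entering, the lists were in macrophage-like cells type I interferon response (0.683), glycolysis and hypoxia (0.879) and adhesion and leukocyte trafficking (0.993), then in T cell-like cells MHC class I antigen presentation (0.967) and glycolysis and hypoxia (0.784). The stricter filter turned in T cell-like cells type I interferon response (0.521), MHC class I antigen presentation (0.671) and glycolysis and hypoxia (0.604), Leiden resolution 2 in microglia-like cells MHC class II antigen presentation (0.676), total counts alone in microglia-like cells TGF-beta and microglial transcription factors (0.965), then in T cell-like cells MHC class I antigen presentation (0.939), fry in T cell-like cells MHC class I antigen presentation (0.981) and glycolysis and hypoxia (0.951), and removal of doublets in T cell-like cells MHC class I antigen presentation (0.783) and glycolysis and hypoxia (0.360).

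Leaving out 1 sample at a time, the number of genes ranged from 0 to 2 in macrophage-like cells and 0 to 3 in T cell-like cells, and with the library set from 33 to 276 in microglia-like, 0 to 10 in macrophage-like, 0 to 10 in T cell-like and 0 to 47 in all cells. Without Sham2, library set 1 holds no Sham sample. Differing effects ranged from 8 to 25 (macrophage-like) and 4 to 41 (T cell-like). Share differences in percentage points ranged from −0.707 to 0.306 for border-associated macrophage-like cells, −0.0465 to 0.0411 for NK cell and ILC1-like cells, −0.0348 to 0.0840 for innate lymphoid cell type 2-like cells, −0.0840 to 0.154 for plasma cell-like cells, −0.243 to 0.690 for neuron-like cells, −0.327 to 0.280 for choroid plexus and ependymal cell-like cells, 9.95 to 13.9 for unnamed cells and −0.774 to 0.0715 for mixed cells, where splits with 6 samples are fewer. Lists called in the 2 classes of brain macrophages, microglia and border-associated macrophage-like cells, ranged from 2 to 9 in microglia-like and 2 to 8 in macrophage-like cells. Adjusted p of lists that turned in at least 1 of these fits ranged in microglia-like cells over type I interferon response 0.00492 to 0.948, TGF-beta and microglial transcription factors 0.396 to 0.949, adhesion and leukocyte trafficking 0.379 to 0.978, MHC class II antigen presentation 0.0835 to 0.763, mitochondrial-encoded transcripts 0.000114 to 0.764, complement 0.0599 to 0.868, lysosome and phagocytosis 0.0386 to 0.949, nuclear-encoded oxidative phosphorylation 0.00492 to 0.901, ribosomal proteins 0.000453 to 0.949, cell cycle 8.6e-05 to 0.978, cholesterol synthesis and efflux 0.407 to 0.978 and T and NK cell activation and cytotoxicity 0.322 to 0.948. In macrophage-like cells it ranged over inflammatory cytokines and NF-kB targets 1.0e-05 to 0.969, immediate early and dissociation response 0.000473 to 0.986, nuclear-encoded oxidative phosphorylation 0.0475 to 0.969, glycolysis and hypoxia 0.322 to 0.986, type I interferon response 0.172 to 0.997, mitochondrial-encoded transcripts 0.00918 to 0.915, lysosome and phagocytosis 0.393 to 0.997, TGF-beta and microglial transcription factors 0.498 to 0.997, adhesion and leukocyte trafficking 0.692 to 0.997 and complement 0.546 to 0.997. In T cell-like cells it ranged over glycolysis and hypoxia 0.506 to 0.952, type I interferon response 0.000366 to 0.924, MHC class I antigen presentation 0.119 to 0.951, nuclear-encoded oxidative phosphorylation 0.0101 to 0.954, mitochondrial-encoded transcripts 0.000159 to 0.912, ribosomal proteins 2.0e-05 to 0.987 and cholesterol synthesis and efflux 0.162 to 0.911. In T cell-like cells the log2 fold change of Rps2 ranged from −0.029 to 0.26 and that of Rps19 from −0.022 to 0.25.

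Only replicate numbers 2 and 4 occur in both groups, and the labels do not say what a number means. With the replicate number as a block, which leaves 1 residual degree of freedom, the genes past the threshold numbered 96 in microglia-like cells, 27 in macrophage-like cells, 25 in T cell-like cells and 82 in all cells, and the lists 12 in microglia-like cells, 9 in macrophage-like cells and 5 in T cell-like cells. Lists that changed direction under the block were in microglia-like cells homeostatic microglia (0.989), nuclear-encoded oxidative phosphorylation (0.00584), mitochondrial-encoded transcripts (0.0746) and ribosomal proteins (4.7e-06), then in macrophage-like cells type I interferon response (0.406), lysosome and phagocytosis (0.448) and TGF-beta and microglial transcription factors (0.406), then in T cell-like cells MHC class I antigen presentation (0.736), nuclear-encoded oxidative phosphorylation (0.930), mitochondrial-encoded transcripts (0.789), glycolysis and hypoxia (0.736) and ribosomal proteins (0.888), and Maf (T cell-like cells, 0.00051) turned as a gene. Samples of numbers 2 and 4 correlated in their deviations at 0.59 and 0.45 in microglia-like, 0.27 and 0.058 in border-associated macrophage-like, 0.15 and 0.17 in T cell-like and 0.72 and 0.37 in all cells. In microglia-like and T cell-like cells Sham2 correlated more with MI1 (0.63 and 0.17), and 2 pairs are too few to establish pairing.

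The deposited files number Sham4 and Sham5 as 3 and 4, which would make 2, 3 and 4 shared, with pairs Sham2 and MI2, Sham4 and MI3, and Sham5 and MI4. These pairs correlated at 0.59, 0.37 and 0.52 in microglia-like and 0.72, 0.27 and 0.36 in all cells, but at 0.27, −0.019 and 0.14 in border-associated macrophage-like and 0.15, 0.027 and 0.081 in T cell-like cells. Each pair lies within a library set, Sham4 correlated more with MI4 than with MI3 in every class, and titles and files disagree, so the samples were not treated as paired. A replicate block by these file numbers, with 2 residual degrees of freedom, called genes numbering 57 in microglia-like cells, 4 in macrophage-like cells, 3 in T cell-like cells and 7 in all cells, and lists numbering 3 in macrophage-like cells. Lists that changed direction were in microglia-like cells nuclear-encoded oxidative phosphorylation (0.0761), mitochondrial-encoded transcripts (0.484) and ribosomal proteins (0.00175), then in macrophage-like cells mitochondrial-encoded transcripts (0.937), lysosome and phagocytosis (0.549), TGF-beta and microglial transcription factors (0.986) and adhesion and leukocyte trafficking (0.937), then in T cell-like cells nuclear-encoded oxidative phosphorylation (0.456), glycolysis and hypoxia (0.588) and ribosomal proteins (0.242), as did Rps12 (T cell-like cells, −0.0025), Rps2 (T cell-like cells, −0.024) and Rps19 (T cell-like cells, −0.0085).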

Other observations

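Microglia-like cells included small clusters with known programmes, whose shares were not tested. Cluster 13, led by the interferon-induced genes Ifit3 and Cxcl10, held 1.85% of Sham and 2.52% of MI microglia-like cells on average; without MI3 the MI mean was 1.73%, below Sham. Cluster 14, led by Lpl, Spp1 and Lgals3, genes of lipid handling and phagocytosis, held 1.68% and 2.10% (1.69% without MI3). Cluster 17, led by the proliferation genes Top2a and Mki67, held 0.920% and 0.695%; without Sham5 the Sham mean was 0.529%, below MI. Cluster 0, led by Ddit4 and Slc2a3, was lower in library set 1 (0.584% in Sham2, 2.78% in MI1 and 5.95% in MI2) than in set 2 (6.83% in Sham4, 22.2% in Sham5, 47.4% in MI3 and 37.5% in MI4).

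Among the unnamed cells, cluster 6 held 24.6% of the cells of MI3 and 14.7% of MI4, against 2.37% to 5.84% in the other samples. Cluster 8, in which neural genes such as Slc1a2 and Aldoc lead cells with microglia markers, held 11.4% of MI1 and 13.1% of MI2, against 1.78% to 5.75% in the others.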
